A study of Rattus norvegicus with 12 samples.

How the data were processed

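Messenger RNA was measured in left ventricle punches from 12 adult rats of the wild-type Groningen strain, 1 library per rat. Per the labels' protocols, 6 rats (RSD) went through social defeat by a resident rat on 8 consecutive days and 6 (CTR) were unhandled controls, and 3' end libraries (QuantSeq forward kit, which reads near the polyadenylated end) were made from 100 ng of total RNA and sequenced on a 100-cycle flow cell. Groups came from the labels, and each library is named by its group and number (CTR 22 to CTR 27; RSD 33, 34, 35, 38, 39 and 40). The groups share no numbers, so no pairing was used. The hour of tissue collection and the order of library preparation are not given in the sources used here.

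The authors deposited 1 table of 32735 rows, each with an Ensembl gene ID and a symbol, with values in CPM (read counts scaled to the same total in every library). The submitters' processing notes name bcl2fastq, STAR 2.6.0a, HTSeq 0.9.1, DESeq2 and the rn6 genome build without their roles; the annotation release is not given in the sources used here. A mark for removal stood on 23030 of the deposited rows and not on 9705; every unmarked row had at least 1 CPM in at least 6 libraries, and no marked row did so in more than 5. Gene names and IDs are those of the table. The gene table supplied for rat is of another assembly, so it was not used and no coordinates are given.

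The low values in each library were whole multiples of 1 step, which gave the number of reads behind each value. Between 99.9% and 100% of the values in a library came out whole within 0.1 read, and the totals were 2062798 to 3731111 reads, with 1 read worth 0.268 to 0.485 CPM. Precision for a gene of a few CPM therefore rests on few reads per library, and intervals hold for the spread between rats, not for molecules counted with identifiers.

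The planned test was the edgeR quasi-likelihood test, which needs counts. Because the deposited unit was CPM, limma took its place, as the design allowed: linear models on log2(CPM + 1) after division by TMM factors (0.914 to 1.12), with an intensity trend in the variance and Benjamini-Hochberg adjustment, two-sided. Fold changes are on this log2(CPM + 1) scale, RSD over CTR, which understates the change of low genes. Genes were kept by the filterByExpr function (minimum count 10) on the recovered reads, leaving 7511. edgeR on the recovered reads was run as an alternative and called 2 genes. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0.

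Of 35 gene lists fixed beforehand, the 26 with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction, were run beside it. The other 9 lists are given as summed CPM; their exact permutation tests were added after the sums had been seen. Library measures were compared by exact two-sided permutation over 924 splits.

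Genes named in the text follow a rule. It takes genes past adjusted p 0.05 with a mean log2 value of at least 1 and a proper symbol (up to 12 per direction), or, since only 2 met this, the 20 with the smallest p; members of each list with the smallest p, up to 4; and 11 fixed genes. How many of the up to 4 members are named for each list, from 1 to 4, was set after the values had been seen, to limit length. In all the rule takes 73 tested genes, of which 1 is not reported here.

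The groups, tests, lists, naming rule and part of the other settings were fixed before the data were examined. Those settings were RLE and upper-quartile factors, no filter, a filter of 50 counts in 6 libraries, limma-voom with quality weights, 1 surrogate variable, DESeq2, other thresholds, both other list tests and leaving out each library. Added after seeing the data were edgeR on recovered reads, pseudocounts of 0.5 and 3, CPM as deposited, the authors' marks as the filter, leaving out the mitochondrial genome, leaving out CTR 22 with RSD 33, the share of the most abundant mitochondrial row as a covariate, and an estimated correlation combined with the 50-count filter, edgeR or limma-voom.

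The models were tested on simulated data with 7514 genes and 200 changed. limma recovered 38.3% of the 60 tested genes changed 1.5-fold, 80% of 60 changed 2-fold and 94.2% of 69 changed 3-fold, with 6 false calls. Many genes changed at once there, which loosens the Benjamini-Hochberg cutoff, and genes were simulated independently. Recovery in the real fit may therefore be lower. When nothing was changed, 0 genes and 0 lists were called. The 0 lists hold for the simulated data only and do not show that camera is calibrated on the real libraries. There, 46 of 100 splits of the 12 libraries, the real one included, called at least the real 3 lists. Correlations estimated between members of the 3 called lists were 0.311 (oxidative phosphorylation), 0.157 (ribosomal proteins) and 0.102 (antioxidant genes), above the preset value. Genes with near-identical copies (Rps23, Cox6b1, Txn1 and the haemoglobin alpha genes) are uncertain, because the names of the value columns end in the word unique, per the file headers, which may leave out reads that fit several copies, and no fuller account is given in the sources used here; 22 tested rows share a symbol with another.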

Results

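The left ventricle of 6 socially defeated rats was compared with that of 6 unhandled rats, to ask how repeated social defeat alters cardiac gene expression. Libraries held 2062798 (RSD 33) to 3731111 (RSD 34) reads, with a mean of 2974068 in CTR and 2872610 in RSD (exact permutation p = 0.719, n = 6 per group). Between 10818 and 11955 genes had a read. The mitochondrial genome took 53.6% ± 2.74 of the reads in CTR and 54.8% ± 3.08 in RSD (SD, n = 6; exact permutation p = 0.5). No pair of libraries held identical values.

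Dbp, a clock-controlled transcription factor (ENSRNOG00000021027), fell from 71.0 ± 14.3 normalised CPM in CTR to 37.9 ± 7.98 in RSD (SD, n = 6 each), a log2 fold change of −0.89 (SE 0.15, limma adjusted p = 0.0147). All 6 RSD libraries lay below the lowest CTR library. Rps23, a protein of the small ribosomal subunit (ENSRNOG00000016580), fell from 34.7 ± 14.8 to 15.3 ± 4.80 normalised CPM (log2 fold change −1.10, SE 0.21, limma adjusted p = 0.0416), with 5 of 6 RSD libraries below the lowest CTR library. These were the 2 genes of 7511 past adjusted p 0.05, and edgeR on the recovered reads and DESeq2 each called the same 2. At an unadjusted p under 0.05 there were 628 genes, 292 higher and 336 lower in RSD, where chance alone gives 376 on average. Chance is not excluded for the 628, since 9 of 100 splits of the 12 libraries, the real one included, gave at least as many. Neither gene passed without CTR 23, CTR 24, CTR 27, RSD 34 or RSD 40 (0 genes in each fit), Rps23 also missed without CTR 25, CTR 26, RSD 33, RSD 35 or RSD 38, and 41 genes passed without CTR 22, Dbp and Rps23 among them. Their log2 fold changes stayed close to those above (Dbp −0.79, −0.80 and −0.90, Rps23 −0.89, −0.95 and −1.11) in 3 fits in which both missed. These were with 1 surrogate variable (0 genes, 368 at an unadjusted p under 0.05), with the share of the most abundant mitochondrial row as a covariate (0 genes, 269 unadjusted) and with no filter on low counts (0 genes, 953 unadjusted).

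**Figure D1:**
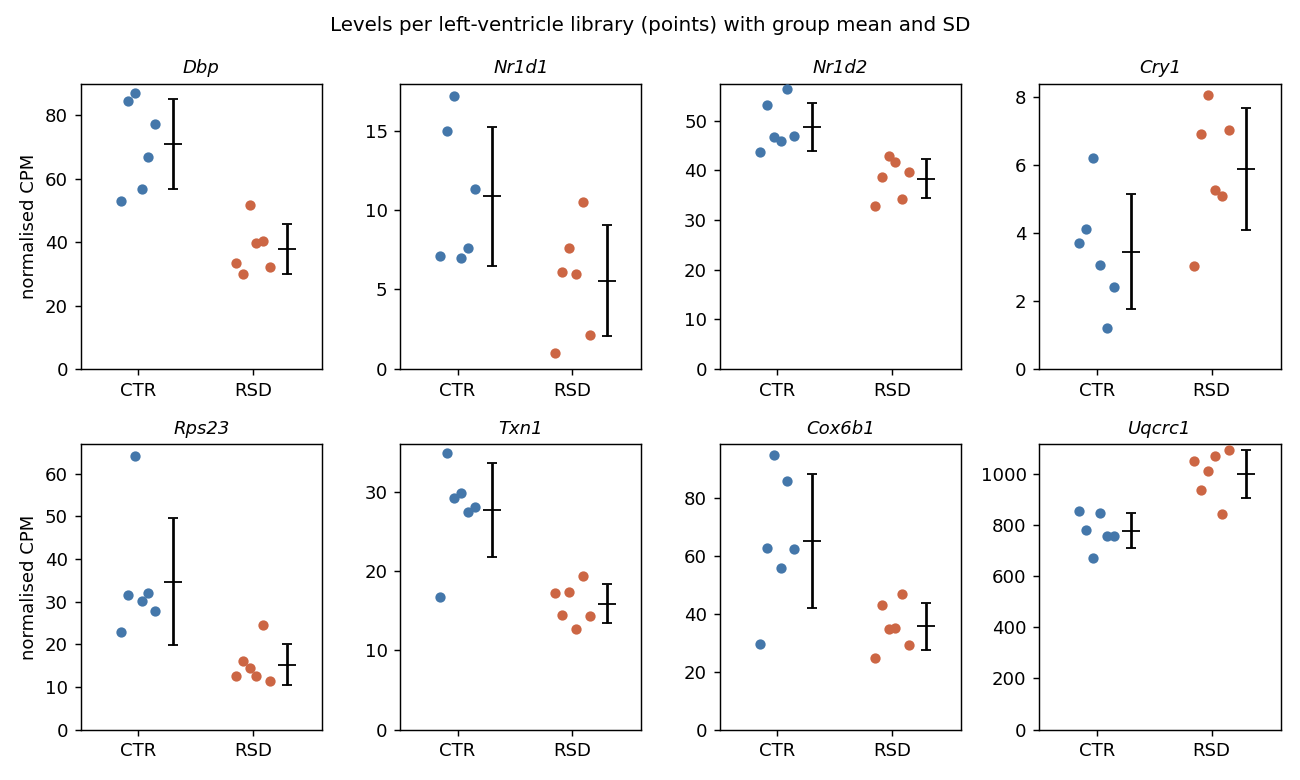
Normalised CPM of 8 genes in each left ventricle library (points), with the group mean and SD beside them (bar), for 6 CTR and 6 RSD rats. Dbp in RSD lies below every CTR library; Nr1d1, Nr1d2, Cry1, Txn1, Cox6b1 and Uqcrc1 did not pass adjusted p 0.05 over all genes.

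Among the other genes with the smallest p, none passed over all genes with the 12 libraries. Without CTR 22, Msrb2 (limma adjusted p = 0.0141), Pcp4l1 (0.0232), Ralgapa1 (0.027), Spag7 (0.0274), Serhl2 (0.0284), Cog6 (0.046) and Zfp207 (0.049) passed. Every other fit without 1 library called 0 to 2 genes. CTR 22 was the control closest to the RSD mean, at 0.951 on an axis from the control mean (0) to the RSD mean (1). The next control stood at 0.463 (CTR 25), and the highest RSD library at 0.784 (RSD 33). Leaving out CTR 22 widens the gap between groups, so passes without it, here and below, are not independent support. Msrb2, a methionine sulfoxide reductase, measured 7.31 ± 3.5 normalised CPM in CTR and 16.3 ± 4.27 in RSD (limma adjusted p = 0.24). Cog6, of the Golgi tethering complex, measured 7.37 ± 2.62 and 2.55 ± 1.12, with all 6 RSD libraries below the lowest CTR library. Zfp207 measured 8.62 ± 2.21 and 15.6 ± 2.18, with all 6 above the highest (limma adjusted p = 0.26 for both). The nearest libraries were 3.67 (RSD 40) and 3.76 (CTR 27) for Cog6, and 11.62 (RSD 40) and 11.57 (CTR 25) for Zfp207. These gaps are smaller than 1 read, and neither separation holds before division by the TMM factors. Pcp4l1 had a log2 fold change of 0.74, Spag7 of −0.56, and Mgp, an inhibitor of calcification, of −0.39. Clk4 measured 5.99 ± 2.50 and 12.8 ± 4.75 normalised CPM. Serhl2 (1.31), Atxn2l (0.72), Ralgapa1 (0.60) and Fcna (0.74) had positive log2 fold changes and Tcp11l2 a negative value of −0.49, each with limma adjusted p = 0.363.

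The circadian clock list had 11 tested members. Adjusted over the list alone, 3 were lower (Dbp, Nr1d1 and Nr1d2) and 0 higher; over all genes 1 passed. Nr1d1, which encodes the repressor REV-ERB alpha, measured 10.9 ± 4.38 normalised CPM in CTR and 5.56 ± 3.51 in RSD. Nr1d2, its paralog, had a log2 fold change of −0.34 (SE 0.13), with all 6 RSD libraries below the lowest CTR library. The gap for Nr1d2 was narrow (42.83 normalised CPM in RSD 35, 43.69 in CTR 22), and the separation does not hold before division by the TMM factors. Cry1, a repressor of the clock, had a log2 fold change of 0.68 (SE 0.30), and missed in both adjustments. Camera did not call the list (limma adjusted p = 0.211), while fry's test for change in either direction did (adjusted p = 0.00659). With the filter of at least 50 counts in 6 libraries camera did call it lower (limma adjusted p = 0.000824, median −0.33; adjusted p = 0.0595 with an estimated correlation under that filter). That filter left out Cry1, which was higher, and Nr1d1, which was lower, since neither reached 50 reads in any library. The call under it is therefore for fewer members than the 11 above. Per1 had a read in 2 of 12 libraries, at most 1.45 CPM, and was not tested.

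Camera on the limma values called 3 lists, all lower in RSD; edgeR and limma-voom also called atrial and red blood cell genes higher (adjusted p = 0.016 and 0.0209 with edgeR, 0.0219 and 0.0486 with limma-voom). With an estimated correlation these gave adjusted p = 0.614 and 0.662 with edgeR and 0.624 for both with limma-voom. The nuclear genes of oxidative phosphorylation, which encode the respiratory chain and ATP synthase, had a median log2 fold change of −0.09 over 74 members, 58 of them below 0 (limma adjusted p = 0.000254; adjusted p = 0.82 with an estimated correlation). The median was −0.15 without CTR 22 and −0.01 with 1 surrogate variable. Adjusted over the list alone 8 rows were lower and 1 higher; over all genes 0 passed, and without CTR 22 9 did (8 lower, 1 higher). Cox6b1 (log2 fold change −0.80, SE 0.20), Cox6a1 (−0.42, SE 0.12) and Uqcrfs1 (−0.49, SE 0.14) were among the lower members, and Uqcrc1, of complex III, was the higher one, at 777 ± 68.3 normalised CPM in CTR and 999 ± 93.9 in RSD. Cox6b1 stands in the table under more than 1 ID, and both of its rows were lower. Ribosomal proteins had a median of −0.12 over 58 members, 42 below 0 (limma adjusted p = 0.00325; adjusted p = 0.819 with an estimated correlation). Rps23 was lower both adjusted over the list alone and over all genes, and the other 57 did not pass; Rpl10 (−0.69), Rpl37a (−0.36) and Rpl37 (−0.26) followed. Antioxidant genes had a median of −0.15 over 19 members, 16 below 0 (limma adjusted p = 0.0351; adjusted p = 0.819 with an estimated correlation). Txn1, thioredoxin, was lower adjusted over the list alone, at 27.7 ± 5.97 and 15.9 ± 2.50 normalised CPM, and 0 members passed over all genes, or 1 (Txn1, limma adjusted p = 0.00852) without CTR 22; Gpx4 (0.31), Sod3 (−0.38) and Sod1 (−0.30) did not pass. With an estimated correlation 0 of 26 lists passed, and 0 by fry in 1 direction; by fry's test for change in either direction 2 passed, the clock list and the antioxidant list (adjusted p = 0.0287). The most abundant mitochondrial row took 19.9% ± 2.80 of reads in CTR and 23.2% ± 2.32 in RSD (exact permutation p = 0.0541, adjusted p = 0.202 over 11 library measures), and with its share as a covariate none of these 3 lists passed, with medians of 0.00 for oxidative phosphorylation and ribosomal proteins and −0.15 for antioxidant genes. With 1 surrogate variable the medians were −0.04 for ribosomal proteins and −0.09 for antioxidant genes, and neither list passed (limma adjusted p = 0.283 and 0.391). The antioxidant list also missed with no filter on low counts (limma adjusted p = 0.0977) and with at least 50 counts in 6 libraries (0.0636). Compared per library, the mean levels of the 3 lists gave exact permutation p = 0.0931, 0.0736 and 0.0541 (adjusted p = 0.205, 0.202 and 0.202 over the same 11 library measures). That adjustment does not cover the choice of these 3 from the 26 lists. CTR 22 had the lowest mean level of oxidative phosphorylation genes, 8.16 on the log2 scale.

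**Figure D2:**
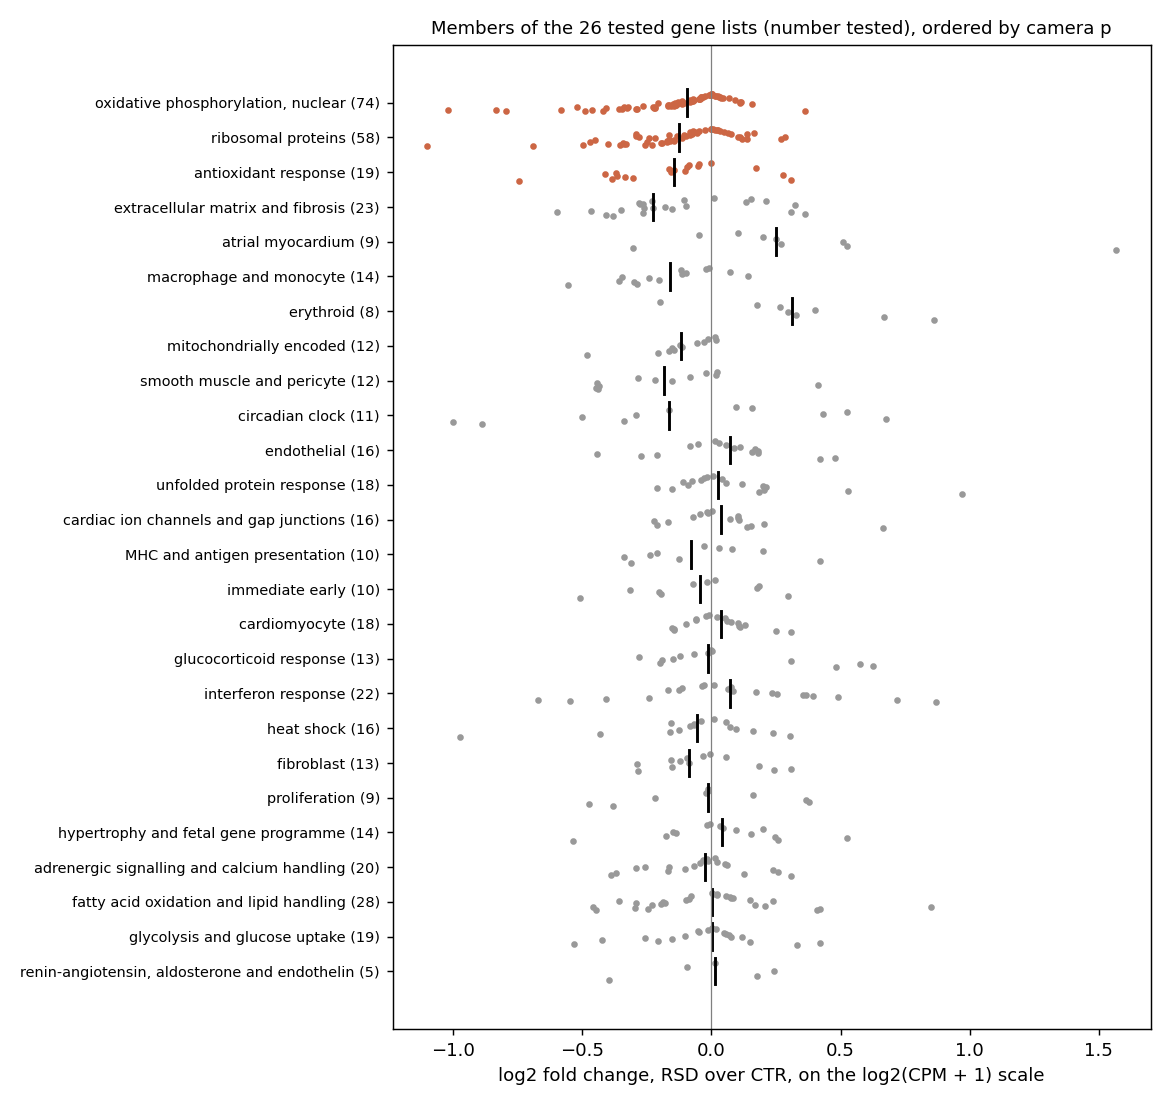
Log2 fold change (RSD over CTR, log2(CPM + 1) scale) of each member of the 26 tested lists (points) with the list median (bar). The 3 lists called by camera with a preset correlation are coloured; their medians are −0.09, −0.12 and −0.15.

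Genes of the glucocorticoid response gave no shared direction, with 13 tested members, a median of −0.01 and a mean of 0.07 (limma adjusted p = 0.727). Nfkbia, which encodes the inhibitor of NF-kappa B, was higher adjusted over the list alone, at 168 ± 47.1 and 233 ± 44.9 normalised CPM, and 0 members passed over all genes, or 1 (Nfkbia, limma adjusted p = 0.0138) without CTR 22. Cdkn1a (0.62), Sgk1 (0.58) and Klf9 (−0.20) did not pass. Fkbp5, a target of the glucocorticoid receptor, had a log2 fold change of −0.15 (95% interval −0.48 to 0.18), and Nr3c1, the receptor, of 0.18 (−0.13 to 0.48).

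Contractile and fetal genes did not pass. Myh6 had a log2 fold change of −0.06 (95% interval −0.27 to 0.15), Myh7 of −0.14 (−0.41 to 0.14) and Nppa, atrial natriuretic peptide, of 0.20 (−0.39 to 0.79), the last of opposite sign without RSD 38 (−0.07). Nppb, brain natriuretic peptide, measured 100.2 ± 24.4 and 70.2 ± 21.6 normalised CPM (log2 fold change −0.54, 95% interval −0.90 to −0.17, limma adjusted p = 0.433). The hypertrophy list had 14 tested members, 0 past the list alone (limma adjusted p = 0.744), with Xirp2 at 0.26. Cardiomyocyte genes (18 tested, adjusted p = 0.727) included Myom2 (0.31) and Mb (0.25). Of 9 atrial genes 7 lay above 0, with a median of 0.25 (limma adjusted p = 0.0921, or 0.819 by camera with an estimated correlation). The list was called higher with 1 surrogate variable (median 0.37, limma adjusted p = 0.0416) and with the mitochondrial covariate. Myl1, an alkali light chain, was higher adjusted over the list alone, at 1.48 ± 1.39 and 6.22 ± 3.33 normalised CPM; Myl4 (0.52), Myl7 (0.51), Tbx5 (0.27) and Dkk3 (−0.30) did not pass, the first 3 of these chosen after their values were seen. Hcn4, the pacemaker channel, was the 1 of 16 ion channel genes higher adjusted over the list alone (log2 fold change 0.66, SE 0.20; list adjusted p = 0.727 by limma's camera). Adrenergic and calcium handling genes had 0 of 20 past the list alone (limma adjusted p = 0.749), with Chrm2 at 0.31 and Gnas at −0.39. Adrb1 had 0 reads in the 12 libraries and was not tested. Whether it was not expressed, or its 3' end reads were not assigned to it, cannot be told here.

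Of 28 fatty acid genes, Plin5, a lipid droplet protein, was higher adjusted over the list alone (log2 fold change 0.41, SE 0.12), while Decr1 (−0.45), Lpl (−0.25) and Plin2 (0.42) did not pass; the list's median was 0.00 and its mean −0.01 (limma adjusted p = 0.749). Of 19 glycolysis genes 0 passed the list alone, with Gys1 at 0.33 and Pdk1 at −0.53, a median of 0.00 and a mean of −0.03 (limma adjusted p = 0.934). Mitochondrially encoded genes had a median of −0.12 over 12 members (limma adjusted p = 0.171), with Mt-nd4l at −0.48. That median was −0.01 without CTR 24, −0.06 without RSD 33 or RSD 38, −0.21 without CTR 22 and −0.18 without RSD 35; the list was called lower without RSD 35 (limma adjusted p = 0.0242) and with limma-voom (0.00909; adjusted p = 0.624 with an estimated correlation). Of 16 heat shock genes Hspe1, a mitochondrial chaperonin, was lower adjusted over the list alone (log2 fold change −0.97, SE 0.27; limma adjusted p over all genes 0.363, and 0.0402 without CTR 22), and Hspb7 had 0.30 (list adjusted p = 0.744 by limma's camera). The unfolded protein response list (18 members, limma adjusted p = 0.646) included Pdia4 at 0.97.

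Extracellular matrix genes had a median of −0.23 over 23 members, 0 past the list alone (limma adjusted p = 0.0921; 0.819 with an estimated correlation). The list was called lower without CTR 23 (0.0397), CTR 26 (0.02), RSD 38 (0.0331) or RSD 39 (0.0254) and with limma-voom (0.0486; adjusted p = 0.624 with an estimated correlation), and its median was −0.15 without CTR 22 and −0.12 without RSD 33. Col3a1 had a log2 fold change of −0.38, Mmp2 of −0.41 and Col1a1 of −0.26 (95% interval −0.55 to 0.02). Of 22 interferon genes, Ifi27l2b was higher adjusted over the list alone (0.87, SE 0.24; limma adjusted p over all genes 0.363, and 0.0402 without CTR 22) and Stat2 had −0.55 (list adjusted p = 0.727 by limma's camera). No member of the following lists passed the list alone, and camera in limma called none of them. They were macrophage (median −0.16, adjusted p = 0.154; Fcer1g −0.56), smooth muscle and pericyte (−0.19, 0.186; Mcam −0.44), endothelial (0.07, 0.646; Eng 0.42 and Tek 0.48) and fibroblast genes (−0.09, 0.744; Gsn −0.28). Antigen presentation (−0.08, 0.727; RT1-Db1 −0.31), immediate early (−0.04, 0.727; Maff −0.51) and proliferation genes (−0.01, 0.744; Pcna −0.38) were likewise not called. Renin-angiotensin genes had a median of 0.01 and a mean of −0.01 (limma adjusted p = 0.986; Ednrb −0.40). Red blood cell genes had a median of 0.31 over 8 members (limma adjusted p = 0.154), with Hba-a2 at 2474 ± 1169 and 4500 ± 3309 normalised CPM and Ahsp at 0.86. Over the 26 lists, 20 members passed adjusted over the list alone (6 higher, 14 lower) and 2 over all genes.

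RSD 40 is labelled female, while the series describes male rats. The Y-linked transcripts Eif2s3y and Kdm5d stood at 7.36 and 10.73 CPM in RSD 40 (24 and 35 reads) and at 7.61 ± 2.17 and 8.31 ± 2.85 in the other 11 libraries, so the sex label of RSD 40 goes against its Y-linked transcripts. Ddx3y, Uba1y, Usp9y and Sry were listed at 0 in all 12 libraries. RSD 40 was kept.

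**Figure D3:**
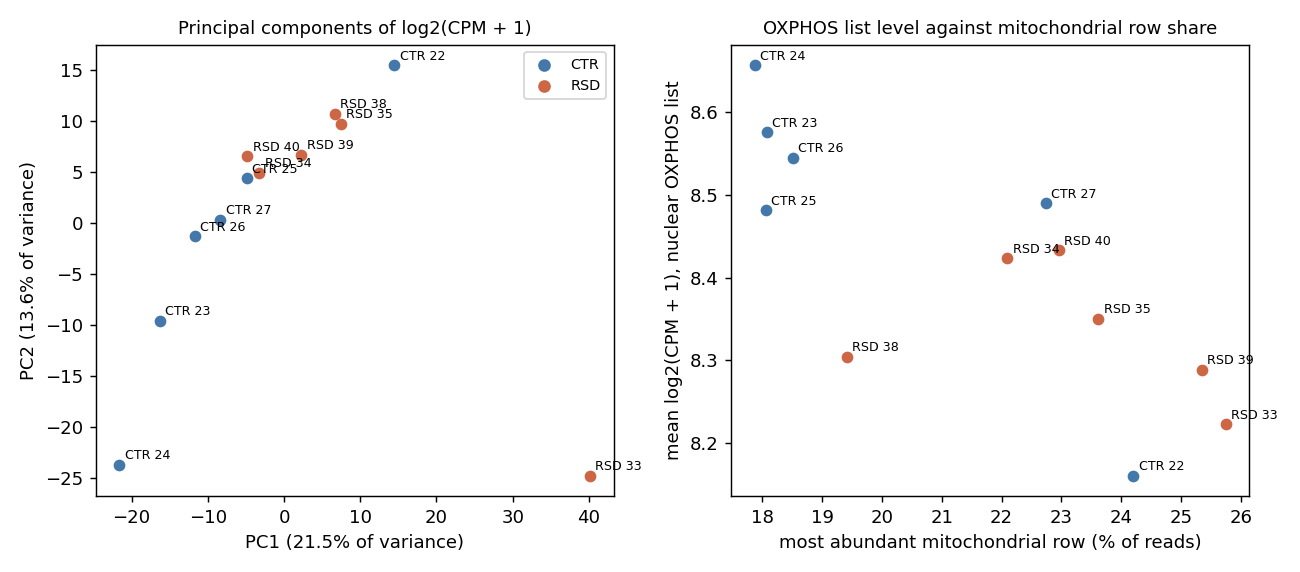
Left, principal components 1 and 2 of log2(CPM + 1) values (21.5% and 13.6% of the variance) for the 12 libraries; right, mean log2(CPM + 1) of the nuclear oxidative phosphorylation genes against the percentage of reads in the most abundant mitochondrial row. RSD 33 lies farthest along component 1 (40.1), and CTR 22 has the lowest oxidative phosphorylation level (8.16).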

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

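The tests of the mitochondrial row on the 3 lists and of clock phase were chosen after the result was seen, as was the check of the mitochondrial covariate without CTR 22. In 7 of 166 group and result pairs 1 library stood apart from the other 5, where chance gives about 8. The gap to the nearest library, as a share of the group's range, was 0.68 for Rps23 in CTR 24 (highest), 0.67 for Txn1 and 0.629 for Pdk1 in CTR 22 (lowest), 0.638 for Zfp207 in RSD 40 (lowest), and 0.654 for Rpl37a and 0.671 for Xirp2 in RSD 33 (lowest). For the mean level of oxidative phosphorylation genes it was 0.646 in CTR 22 (lowest).

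Chance cannot be excluded for any of the 3 summary counts. Of 100 splits of the 12 libraries, the real one included, 6 called at least the real 2 genes (highest other split 6 genes), 46 called at least the real 3 lists (highest other 7), and 9 gave at least the real 628 genes past unadjusted p 0.05 (highest other 962).

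The lists for oxidative phosphorylation, ribosomal proteins and antioxidant genes were called lower in RSD with a preset correlation, a call lost with an estimated one (adjusted p = 0.82, 0.819 and 0.819 by limma's camera). Thinning every library to the lowest total kept at least 0.993 of each median. Random thinning leaves the expected CPM unchanged, so this check could hardly come out otherwise and does not decide on unequal depth. A shift in the share of the most abundant mitochondrial row stays open. Within groups the mean of the 3 list scores correlated with that share at Pearson r = −0.634 (permutation p = 0.0359, Spearman rho −0.45). The Pearson value was −0.787 in CTR alone and −0.241 in RSD alone. Without CTR 22 and CTR 27 it was −0.421, so the relation leans on those libraries. With the share as a covariate the medians of oxidative phosphorylation and ribosomal genes came to 0.00, while the antioxidant median stayed at −0.15, and the share differs in part with the group, so share and defeat cannot be told apart here. A response to defeat stays open too, and chance was not excluded.

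Dbp was lower in RSD. The library trend in oxidative phosphorylation is argued against as the whole cause: with its score as a covariate the log2 fold change was −0.747 (95% interval −1.07 to −0.42) against −0.89 without, and the call ended (limma adjusted p = 0.185) as the estimate became smaller and less certain. A shifted clock phase, from defeat or from the hour of sampling, is a candidate explanation: Clock, Cry1 and Nfil3 exceeded Nr1d1, Nr1d2, Tef and Per3 by 0.731 in mean log2 fold change (exact permutation p = 0.00216), although Per3 (0.52) went against it; those genes were picked after the values were seen, and with Per2 (0.16), Cry2 (−0.29) and Bhlhe41 (−0.16) added to the second set, a test also chosen afterwards, the difference was 0.633 (exact permutation p = 0.00216). The hour of sampling is not given in the sources used here, so those sources of a shift were not separated.

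Leaving out CTR 22 raised the count from 2 to 41 genes. On an axis from the control mean (0) to the RSD mean (1) of the other 11 libraries CTR 22 stood at 0.951. It was above every RSD library (highest 0.784, RSD 33), and 3 RSD libraries lay below the middle (RSD 34 0.439, RSD 39 0.485, RSD 40 0.435). A swap or a single wrong label may therefore account for the rise in the count. Positions of left-out libraries shrink toward the middle, however, and natural variation of 1 rat stays open too. The mitochondrial share as a covariate gave 0 genes over 12 libraries, below the bound of 10 set beforehand against it. That bound was wrong, because the same covariate also took the fit without CTR 22 from 41 genes to 1, so the share cannot be told apart from the other explanations.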

How the results depend on the processing

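Alternatives chosen after seeing the data were edgeR, the pseudocounts, CPM as deposited, the authors' marks, the fit without mitochondrial genome rows, the fit without CTR 22 and RSD 33, the mitochondrial covariate, and an estimated correlation with at least 50 counts, edgeR or limma-voom. The 2 genes were called again with RLE and upper-quartile factors, DESeq2, edgeR, both pseudocounts, CPM as deposited, the authors' marks and no mitochondrial genome rows; limma-voom called 3, both among them. The count was 0 with no filter on low counts (953 at an unadjusted p under 0.05), 0 with 1 surrogate variable (368), 0 with the mitochondrial covariate (269), 1 with at least 50 counts in 6 libraries, and 37 without CTR 22 and RSD 33. Leaving out each library gave 0 (CTR 23, CTR 24, CTR 27, RSD 34 or RSD 40; 450 to 687 unadjusted) to 41 (CTR 22). List members past adjusted p 0.05 over all genes, 2 in the report, numbered 0, 0, 0, 1 and 12 in those same settings and 0 to 15 with each library left out. Over these settings Dbp's log2 fold change lay between −0.98 and −0.79, and with the oxidative phosphorylation score as a covariate it was −0.747.

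Lists called, 3 in the report, numbered 7 with limma-voom (5 lower; atrial and red blood cell genes higher), 5 with edgeR (3 lower; the same pair higher), 1 with 1 surrogate variable and 1 with the mitochondrial covariate (atrial myocardium, higher, in both), 0 with an estimated correlation, 0 with fry, and 2 to 6 with each library left out. The limma adjusted p, by camera with 1 surrogate variable, camera with an estimated correlation, fry, and camera with the mitochondrial covariate, was 0.619, 0.82, 0.554 and 0.84 for oxidative phosphorylation, 0.283, 0.819, 0.554 and 0.604 for ribosomal proteins, and 0.391, 0.819, 0.554 and 0.234 for antioxidant genes. With an estimated correlation at 50 counts, with edgeR and with limma-voom, 0 lists passed in each, and adjusted p was 0.857, 0.662 and 0.624 for oxidative phosphorylation and 0.7001, 0.614 and 0.624 for both ribosomal proteins and antioxidant genes. The circadian clock list was called lower with at least 50 counts in 6 libraries (0.000824), on fewer members, without Cry1 and Nr1d1. The antioxidant list also missed with no filter (0.0977), at least 50 counts (0.0636) and the authors' marks (0.0714), and ranged from 0.00496 (without CTR 22) to 0.0946 (without CTR 27). The sign turned for Fkbp5 with 1 surrogate variable (0.00556) and the mitochondrial covariate (0.0587), for Myh7 with that covariate (0.10) and for Nppa without RSD 38 (−0.0676, up to 0.551 without RSD 35), none past the threshold. The cause was not tested. At these depths and with 6 rats per group, limma recovered 38.3% of simulated genes changed 1.5-fold. With 200 genes changed at once and genes simulated independently, that share may overstate recovery in the real fit. The shares of depth and of spread between rats in that recovery were not tested.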

Other observations

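The test of the 3 rows without a gene name was on rows picked after their values were seen, and the permutation tests of summed levels were chosen after the sums were seen. Immune and other cell markers with too few tested genes for a list test were summed. Mast cell markers summed to 13.3 ± 3.06 CPM in CTR and 8.71 ± 2.22 in RSD (SD, n = 6; exact permutation p = 0.0152, adjusted p = 0.136 over 9 lists), and T and NK cell markers to 41.2 ± 6.98 and 32.9 ± 4.44 (exact permutation p = 0.039, adjusted p = 0.175). Neither passed the correction. Inflammatory cytokine and adhesion genes summed to 267 ± 56.6 and 318 ± 25.6, neutrophil markers to 11.05 ± 11.8 and 3.85 ± 3.22, and B and plasma cell markers to 2.24 ± 1.22 and 2.69 ± 0.53. Nfkbia, which encodes an inhibitor of NF-kappa B, made up most of the first sum (168 ± 47.1 in CTR and 233 ± 44.9 in RSD, normalised CPM). That sum therefore does not show a rise of the other members. Adipocyte markers summed to 153 ± 18.1 and 159 ± 52.4, Schwann cell and neuron markers to 18.0 ± 4.29 and 17.0 ± 2.81, epicardial markers to 12.6 ± 4.26 and 15.0 ± 4.88, and lung markers to 7.18 ± 2.40 and 6.31 ± 0.517 CPM. None of the 9 sums passed (lowest adjusted exact permutation p = 0.136).

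The levels of 3 rows without a gene name varied between rats. ENSRNOG00000062158 stood at 9089 ± 6380 CPM in CTR and 12788 ± 8683 in RSD, ENSRNOG00000062127 at 411 ± 334 and 635 ± 339, and ENSRNOG00000062155 at 18.2 ± 13.01 and 30.2 ± 11.8 (SD, n = 6), with limma adjusted p from 0.367 to 0.665. Without CTR 22, ENSRNOG00000062155 (log2 fold change 1.16, limma adjusted p = 0.0136) and ENSRNOG00000062127 (1.16, 0.027) passed. The hypothesis that they follow RNA from red blood cells was tested against the haemoglobin alpha genes. Over the 12 libraries the lowest of the 3 Pearson correlations was 0.109 (permutation p = 0.735; Spearman rho 0.24, permutation p = 0.444; adjusted p = 0.735 over 3 rows), where the hypothesis needed over 0.8. The bound set beforehand against the hypothesis, at least 1 row under 0.3, was met, with the other values at 0.176 and 0.151. Without RSD 34 and RSD 35, a check that was not part of that bound, the 3 values were 0.327, 0.42 and 0.451. These were above 0.3 but still under 0.8. The values argue against these 3 rows closely following the haemoglobin alpha genes (r over 0.8). A weaker relation stays open, since all 3 values rose without RSD 34 and RSD 35, and no other red cell marker was used.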
